A study of Rattus norvegicus with 31 samples.

How the data were processed

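RNA from fat tissue of male Sprague-Dawley rats was sequenced in 31 libraries. Perivascular adipose tissue (PVAT), the fat that surrounds the thoracic aorta, was dissected above and below the position of an aortic ligature, and brown adipose tissue (BAT) was the other kind of sample. The ligature was tied in the coarctation groups and left loose in the sham groups, and the labels state an RNA integrity number of at least 7.5. The libraries fell into 6 groups by surgery and site.

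The authors deposited a table of whole-number read counts per Ensembl gene, with 1 column per library and no normalisation. The authors also deposited an FPKM table, which scales fragments to gene length and library total. The FPKM values were checked against the counts and equalled count divided by 1 length per gene and by the library total, with a largest relative deviation of 5.11e-15. Per the labels, STAR 2.5, HTSeq 0.6.1 and DESeq2 1.24.0 were used upstream, without a statement of which step used which settings. The genome build and the annotation release are not given in the sources used here. A second FPKM table held the same columns and was not used here.

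The count table had 32883 gene entries, of which 8811 had no count in any library. For 25 entries the count table held a date in place of the gene name, and the name of the FPKM table was taken. Library totals ran from 15713160 to 26530733 counts. Counts scaled to the library total (CPM) are given as mean ± SD over the libraries of a group. Intervals on ratios of low counts are exact binomial 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

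Genes were tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 5 PVAT comparisons shared a fit of 22 libraries in 4 groups, the BAT comparison used 9 libraries, and the comparisons of PVAT with BAT used 14 sham libraries in 3 groups. An interaction contrast tested whether the difference between sites differed with surgery. The p-values measure the spread between these samples. Each SE of a log2 difference was derived from the test, as the absolute difference divided by the square root of F. The 8 comparisons, the tests, the 38 gene lists, the rule for naming genes and the first set of alternatives were chosen before the data were examined.

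The 38 lists held 827 genes, of which 781 were in the table, and covered adipocyte function, matrix, vessel, immune, muscle, nerve, epithelial, stress and positional genes. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The summed CPM of 14 lists of other cell types was compared between groups with 2-sided exact permutation tests, adjusted over all 98 of them. Genes were named by a rule. Among called genes that have a symbol, it took the 8 largest rises and the 8 largest falls with a mean log2 CPM of at least 1. Where fewer than 10 such genes passed, it took those that passed and the lowest p-values up to 10. It added 2 members of each called list for up to 6 lists, and a set of fixed genes (Ucp1, Adipoq, Lep, Col1a1, Col3a1, Acta2, Myh11, Agt, Ctgf, Cd68 and Pdgfra; Pecam1, also fixed, had no entry). Any other gene that is named was chosen after its values were seen.

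The alternatives chosen in advance were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, limma on log2(FPKM + 1), another set of libraries for the estimate of the spread, a minimum log2 fold change of 1, a block for the number in the sample titles, and leaving out each library in turn. Titles give libraries of several sites the same number, and no source states that a number is 1 rat. The numbers were taken to pair the libraries of a comparison where the deviations of every same-number pair from the group means correlated over 0.1. This held for 6 of 6 pairs of coarct above and below (0.102 to 0.55) and 4 of 4 of sham below and BAT (0.228 to 0.419), a check made by comparison after the counts with and without the block were seen. The same-number pairs of sham above 20 and 24 fell short of this over all genes. On the 200 genes that varied most between the other numbers, these pairs correlated at 0.426 to 0.68. The rule may therefore miss numbers that pair the libraries. Other alternatives were added after seeing the data. The libraries split by reads of mitochondrial rRNA into 17 with and 14 with few such reads, at 512 CPM of 12S rRNA, a level chosen after seeing the values. This split was used as a term and in separate fits of both sides. Further fits left out 3 libraries that stood apart on the first principal component, left out 5 PVAT libraries with neuron transcripts, or used the summed muscle and neuron transcripts as covariates. The trend of each library on gene length was measured as the slope of its log2 deviations from the mean of all libraries on log2 length, and its Spearman rho with list sums was taken after seeing the data. The tests were also tested on simulated data with known changes added to the real group sizes and spread. Many genes were changed at once, by 1.5-fold to 8-fold, and each gene was drawn independently of the others. No reference genome was at hand, so sequence-based checks were not run.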

Results

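Bulk RNA sequencing compared fat around the thoracic aorta with brown fat in rats with a coarctation, a narrowing of the mid-thoracic aorta that leaves higher pressure above it than below it. The labels state a systolic gradient of about 20 mmHg at 4 weeks after surgery, an age of 10 to 15 weeks and a time point of 15 weeks. Coarcted rats gave 6 libraries of PVAT above the ligature (coarct above), 6 of PVAT below it (coarct below) and 5 of BAT. Sham-operated rats gave 5 libraries of PVAT above the loose ligature (sham above), 5 below it (sham below) and 4 of BAT. Total counts per library were 18256260 to 23874564 in coarct above, 16974982 to 23255559 in coarct below and 16232414 to 21648074 in coarct BAT. They were 17749979 to 19345593 in sham above, 15713160 to 20888691 in sham below and 17112122 to 26530733 in sham BAT. Brown adipocyte transcripts were abundant in every group, with Ucp1, the uncoupling protein of heat production, at 1820 ± 515 CPM (SD, n = 5) in sham above and 1360 ± 174 CPM (n = 4) in sham BAT.

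PVAT held transcripts of other tissues in amounts that differed between libraries. The median summed CPM of the cardiac muscle list was 679 in coarct above and 938 in sham above, against 11.5 in coarct below and 13.1 in sham below. Coarct above replicate 30 held few of these transcripts, with 8.59 CPM. Coarct below replicate 25 had a list sum of 675 CPM, beside 3834 CPM of the skeletal muscle list. It held only 0.236 CPM of Tnnt2, 0.884 CPM of Actc1 and 10.5 CPM of Myh6, so that other list members made up most of its sum. Among the shams, above replicate 20 held 50.6 CPM, against 777 to 1955 CPM in the other 4. Below replicates 22 and 28 had list sums of 113 and 94.2 CPM, beside 1297 and 832 CPM of the skeletal muscle list. The cardiac genes Myl7 and Tnnt2 had only 3 and 2 counts over all 5 sham below libraries. The sympathetic neuron list reached 426 to 1065 CPM in 4 of the 6 coarct below libraries and 667 CPM in 1 of the 5 sham below libraries, replicate 28. The highest of the other libraries had 33.2 CPM. Mesothelial transcripts, from the cell layer that lines the chest cavity, had median sums of 91.4 CPM in sham above, 78.8 CPM in sham below and 7.63 CPM in sham BAT. None of the 98 exact permutation tests on such sums passed after adjustment, the lowest adjusted p being 0.388, but the design left little room: the smallest p that the group sizes allow is 0.00216 to 0.0159, so that a test alone in reaching it would have an adjusted p of at least 0.212.

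**Figure D1:**
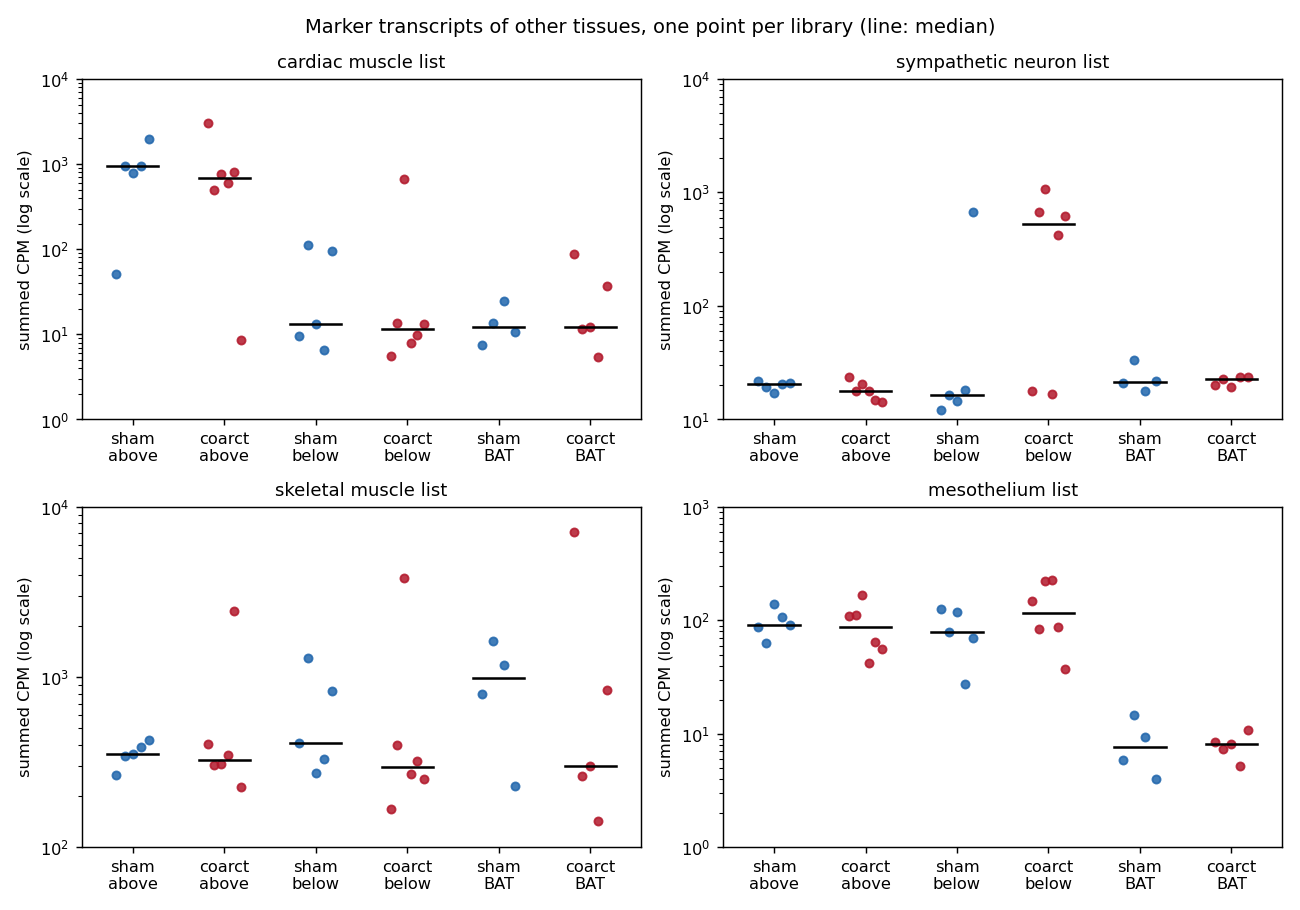
Summed CPM per library (log axis) of the cardiac muscle, sympathetic neuron, skeletal muscle and mesothelium lists in the 6 groups, with 1 point per library (blue, sham; red, coarctation) and a line at each group's median. Cardiac sums were high above the ligature in both surgeries, with medians of 679 and 938 CPM, and neuron sums were high in 4 coarct below libraries and 1 sham below library.

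The comparison of coarct above with sham above asked how PVAT under raised pressure differs from PVAT at the same site without it, and no gene passed the test. Lep, which encodes the adipocyte hormone leptin (ENSRNOG00000045797, chromosome 4, start 56337695), measured 236 ± 89.1 CPM (SD, n = 6) in coarct above and 132 ± 52.0 CPM (n = 5) in sham above. Its log2 difference was 0.88 (SE 0.342, edgeR adjusted p = 0.999), with 5 of 6 coarct libraries above the sham median. The lowest p belonged to Chst15, a sulfotransferase of chondroitin sulfate, at 6.29 ± 0.674 CPM (n = 6) against 3.75 ± 0.902 CPM (n = 5), a log2 difference of 0.80 (edgeR adjusted p = 0.404). Pik3r1, the regulatory subunit of a kinase of insulin signalling, measured 109 ± 39.6 CPM against 52.1 ± 22.8 CPM (edgeR adjusted p = 0.999). Ucp1 differed by -0.11 and Col1a1, a fibrillar collagen chain, by -0.29 on the log2 scale.

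By gene group, all 19 measured macrophage genes and all 11 erythroid genes had lower fitted levels in coarct above, with median log2 differences of -0.35 and -0.70. Camera gave adjusted p = 6.72e-07 and 3.59e-05, and adjusted p = 0.546 for both with an estimated correlation. The T cell list had a median of -0.39, the B cell list -0.45 and the Schwann cell list, of nerve sheath cells, -0.62, with adjusted p = 0.546, 0.274 and 0.546 with an estimated correlation. The summed B cell level was close in both groups, with medians of 97.3 and 96.2 CPM, and sham above replicate 22 had the highest Schwann cell sum, at 710 CPM against a median of 410 CPM in the others. Of 10 B cell genes none passed over all genes and 3 were lower when adjusted over the list alone. Fatty acid and triglyceride synthesis genes lay higher in 19 of 20 cases, with a median of 0.28 and adjusted p = 0.00256, or adjusted p = 0.546 with an estimated correlation. Immediate early genes, which respond to stimuli within minutes, had a median of -0.60, and Nr4a3 varied widely in sham above, at 7.90 ± 12.3 CPM (n = 5) against 0.852 ± 0.522 CPM (n = 6); the list's adjusted p = 0.000186 became adjusted p = 0.546 with an estimated correlation. The list's sum was high in sham above 20 and 24, at 1192 and 884 CPM, and the other 3 sham libraries, at 312 to 432 CPM, lay within the range of coarct above, 299 to 530 CPM. In all, 12 of 35 lists were called and 0 with an estimated correlation, and 19 were called without coarct above replicate 19.

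Over 14556 genes, edgeR called 0, with 523 at an unadjusted p under 0.05 where 728 would arise by chance. DESeq2 called 6, of which Chst15 and Vps35l were higher, limma called 0, and edgeR called 0 within each side of the mitochondrial rRNA split. Lep differed by 0.48 within the 17 libraries with mitochondrial rRNA reads and by 1.20 within the 14 with few. In simulated data of this design, 30 of 50 genes changed by 2-fold and 41 of 50 changed by 4-fold were found. Many genes were changed at once there and genes varied independently, so that a smaller share may be found where few genes change. False calls in the same data numbered 5 by edgeR and 20 by DESeq2.

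Coarct below was compared with sham below to ask whether surgery alters PVAT on the low-pressure side, and again no gene passed. Lep measured 229 ± 102 CPM (SD, n = 6) in coarct below and 112 ± 47.5 CPM (n = 5) in sham below, a log2 difference of 0.90 (SE 0.342, edgeR adjusted p = 0.881), higher than the sham median in 5 of 6 libraries. Enc1, an actin-binding protein, had the lowest p, at 53.6 ± 10.5 CPM against 73.3 ± 11.4 CPM, a log2 difference of -0.57 (edgeR adjusted p = 0.536). Dusp4, a phosphatase that turns off MAP kinases, measured 75.2 ± 24.9 CPM against 142 ± 67.9 CPM, lower than the sham median in 6 of 6 libraries (edgeR adjusted p = 0.881).

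Respiratory chain genes encoded in the nucleus lay lower in all 36 measured cases, with a median log2 difference of -0.16 and adjusted p = 1.63e-08, or adjusted p = 0.566 with an estimated correlation. Their summed level moved with the gene length slope over the 11 libraries (Spearman rho -0.791), from 20190 CPM at a slope of 0.194 in sham below 28 to 26810 CPM at -0.133 in sham below 24. The 13 mitochondrially encoded genes also lay lower in each case, by a median of -0.19, with adjusted p = 0.594 with an estimated correlation. Matrix structure genes were higher in 30 of 35 cases, by a median of 0.19, with adjusted p = 0.00351, or 0.795 with an estimated correlation. Sympathetic neuron genes lay higher in all 18 cases, by a median of 1.59, and Schwann cell genes in 14 of 16, by 0.73, with adjusted p = 0.566 for each with an estimated correlation. Both lists moved with the neuron transcripts of 4 coarct below libraries, whose summed level did not pass against sham below (exact permutation p = 0.13, adjusted p = 0.671). No member of these lists passed over all genes or adjusted over the list alone.

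EdgeR called 0 of 14556 genes, with 746 at an unadjusted p under 0.05 against 728 by chance. DESeq2 called Enc1 alone, limma called 0, and 0 were called within each side of the rRNA split, where sham below had 1 library with few such reads. Leaving out sham below replicate 28, the sham library with neuron transcripts, gave 169 genes, 154 higher and 15 lower, of which 14 were on the neuron list.

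**Figure D2:**
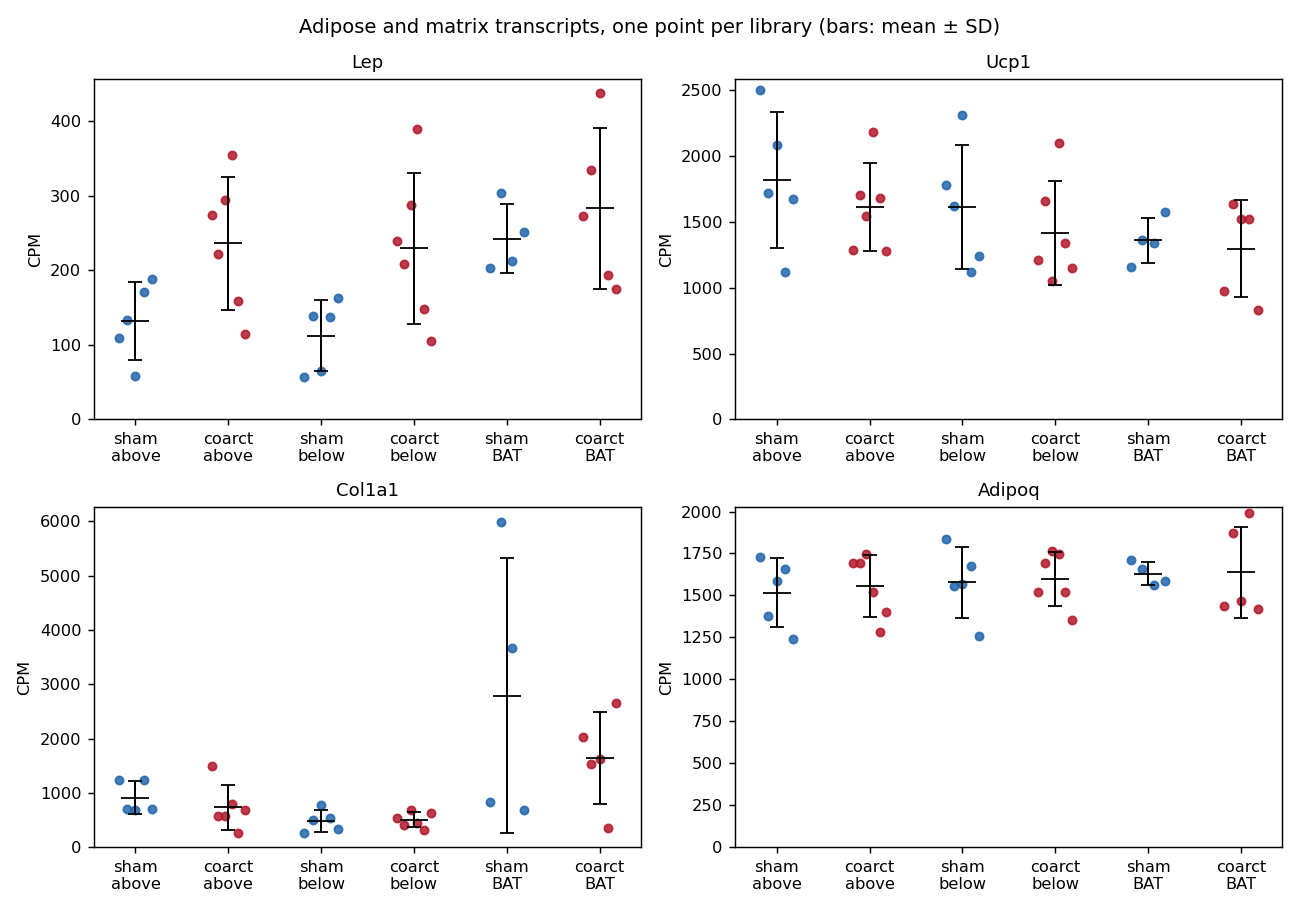
CPM per library of Lep, Ucp1, Col1a1 and Adipoq in the 6 groups, with 1 point per library and the mean ± SD. Mean Lep was 236 CPM in coarct above and 132 CPM in sham above, a difference that did not pass the test, and Ucp1 and Adipoq were abundant in all 6 groups.

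Within coarcted rats, PVAT above and below the ligature was compared as the 2 sides of the pressure gradient. Heart muscle genes were far higher above it: Myl7, the atrial myosin light chain (ENSRNOG00000014409, chromosome 14, start 86143862), measured 147 ± 150 CPM (SD, n = 6) above and 0.0892 ± 0.0797 CPM (n = 6) below. Its log2 difference was 10.53 (SE 1.30, edgeR adjusted p = 0.000638), with 5 of 6 libraries above the median of the other site. Tnnt2 and Tnni3, troponin subunits of heart muscle, rose by 10.29 and 9.05, and Ankrd1, a stretch-responsive protein of heart muscle, by 6.73 (edgeR adjusted p = 0.00107). Pln, which regulates calcium uptake in heart and smooth muscle, rose by 3.73 (SE 0.554, edgeR adjusted p = 0.00201). Genes that fell were Tspan8, a tetraspanin, by 0.60 on the log2 scale, at 9.85 ± 1.64 CPM against 15.4 ± 2.94 CPM (edgeR adjusted p = 0.0379), and Arnt2, a transcription factor, by 2.08 on the log2 scale (SE 0.362, edgeR adjusted p = 0.0124). Arnt2 was chosen after its values were seen.

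Of 13 measured cardiac muscle genes, 7 rose; adjusted over the list alone, 9 rose and 1, Myl3, a light chain of slow and ventricular muscle chosen after its values were seen, fell, with a list adjusted p = 0.00538 with an estimated correlation. The sums of the cardiac list differed between sites with exact permutation p = 0.0433, which did not pass after adjustment. Sympathetic neuron genes were lower above in all 18 cases, by a median of -5.44; none passed over all genes, 17 passed adjusted over the list alone, and the list held at adjusted p = 0.0363 with an estimated correlation. Prph, a neuronal filament protein, measured 4.04 ± 1.12 CPM above and 52.9 ± 42.1 CPM below (edgeR adjusted p = 0.076), and Uchl1, a neuronal ubiquitin hydrolase, 0.190 ± 0.139 CPM and 31.7 ± 29.3 CPM (edgeR adjusted p = 0.076). The neuron-rich libraries were coarct below replicates 23, 25, 29 and 30.

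Vascular smooth muscle genes rose as a list (adjusted p = 0.0363 with an estimated correlation), with Pln the only member of 20 past the test over all genes and 3 past it adjusted over the list alone. Their summed level was close at both sites, with medians of 1100 CPM above and 1048 CPM below (exact permutation p = 0.673). Casq2, a calcium store protein of heart and smooth muscle, measured 20.5 ± 19.3 CPM against 4.56 ± 6.08 CPM, beside cardiac sums with medians of 679 CPM above and 11.5 CPM below. B cell genes were lower above in 9 of 10 cases, by a median of -0.64, and the list fell (adjusted p = 0.0363 with an estimated correlation). The summed B cell level differed by -0.116 on the log2 scale, with medians of 97.3 CPM above and 106.6 CPM below (exact permutation p = 0.219). It was lower than the median below in 6 of 6 libraries. Nuclear respiratory chain genes lay higher above in 34 of 36 cases, by a median of 0.11, and cell cycle genes in 25 of 28, by 0.28, with adjusted p = 0.656 and 0.372 with an estimated correlation. Coarct above replicate 19 had the highest cell cycle sum, 137 CPM, and the other 5 lay at 72.0 to 92.2 CPM, against 71.9 to 93.5 CPM below. Lep, at a log2 difference of 0.08, and Adipoq, at 0.01, were close at both sites, with edgeR adjusted p = 1.0 for each.

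EdgeR called 15 of 14556 genes, 13 higher and 2 lower, against 235 by DESeq2, 4 by limma, 5 with the spread of both groups alone, 0 within the 17 libraries with mitochondrial rRNA reads and 9 within the 14 with few. Among the 17, coarct above 30 held 8.59 CPM of cardiac transcripts, against 3072 and 812.5 CPM in coarct above 19 and 29. The coarct above libraries among the 14 held 498 to 760 CPM. Coarct below 25 was among the 14 too, and its 675 CPM came mostly from list members other than Tnnt2, Actc1 and Myh6. With the title number as a block 42 genes were called, 15 higher and 27 lower, and Tspan8 was not (edgeR adjusted p = 0.0578). Without coarct below replicate 19 or 27, the libraries lacking neuron transcripts, the counts were 185 and 180. With the muscle and neuron sums as covariates 1 gene was called, Csrp3, a muscle LIM protein. The cardiac sum contains called cardiac genes and differed between the sites by 4.31 on the log2 scale, so that the loss of their calls was largely built in. Without the 5 neuron-rich PVAT libraries 1 was called, an uncharacterised locus, in a fit that left only replicates 19 and 27 in coarct below. Csrp3 and that locus were chosen after their values were seen. Myl7 differed by 12.04 within the 17 libraries (edgeR adjusted p = 1), where 2 of the 3 below had 0 counts, and by 9.58 within the 14 (edgeR adjusted p = 0.00048), and Tspan8 by -0.56 and -0.62, past the test in neither. Tspan8 was lost without any of 9 libraries (adjusted p 0.0509 to 0.122), namely coarct above 19, 23, 25, 27 or 29 and coarct below 23, 25, 29 or 30.

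Sham above was compared with sham below for regional differences without a pressure gradient. Cardiac genes were again higher above: 13908 counts of Myl7 were found above and 3 below, a ratio of 4620 with a 95% counting interval of 1580 to 22400. Tnnt2 had 7724 counts above and 2 below, a ratio of 3850 (1060 to 31800). Ankrd1 rose by 6.59 on the log2 scale (SE 1.01, edgeR adjusted p = 0.00513) and Pln by 3.85 (SE 0.612, edgeR adjusted p = 0.00513), each higher than the median below in 5 of 5 libraries. Of the 13 genes that rose in coarcted rats and the 10 that rose in shams, 10 were shared, where 0.00893 would be shared by chance.

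Of 13 cardiac muscle genes, 6 rose over all genes and 9 adjusted over the list alone, and the list held at adjusted p = 0.00741 with an estimated correlation. Macrophage genes lay higher above in all 19 cases, by a median of 0.45, with adjusted p = 1.36e-09, or adjusted p = 0.28 with an estimated correlation. C1qa, a complement subunit made by macrophages, measured 53.6 ± 18.2 CPM (SD, n = 5) above and 30.6 ± 12.3 CPM (n = 5) below. Matrix structure genes lay higher in 28 of 35 cases, by a median of 0.36, with adjusted p = 0.28 with an estimated correlation. Fn1, the matrix protein fibronectin, measured 347 ± 118 CPM against 163 ± 43.4 CPM (edgeR adjusted p = 0.418), and Col1a1 916 ± 303 CPM against 487 ± 201 CPM (edgeR adjusted p = 0.891), both higher in 5 of 5 libraries. Fatty acid and triglyceride synthesis genes lay lower in 17 of 20 cases, by a median of -0.45, with adjusted p = 0.406 with an estimated correlation. Sympathetic neuron genes lay lower in 18 of 18, by a median of -3.35, and 11 of them were lower adjusted over the list alone. Sham below replicate 28 held 667 CPM of their transcripts, and the direction turned in the sums of the rest. The other 4 libraries below held 12.2 to 18.2 CPM, and 5 of 5 above lay over the median below (20.6 against 16.3 CPM). With replicate 28 included, the mean log2 difference of the sums was -0.71 (exact permutation p = 0.992), and the rest were not tested alone. That list's adjusted p = 0.00531 became adjusted p = 0.563 with an estimated correlation.

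EdgeR called 10 of 14556 genes, all higher, with 776 at an unadjusted p under 0.05, against 44 by DESeq2, 7 by limma and 23 without sham above replicate 20. With the title number as a block more genes were called, as given in the section on processing. Within the 17 libraries with mitochondrial rRNA reads 0 genes were called. Sham above 20 and 26, the sham above libraries there, held 50.6 and 938 CPM of cardiac transcripts. Sham below 22 and 28, also among the 17, had cardiac list sums of 113 and 94.2 CPM, beside 1297 and 832 CPM of the skeletal muscle list. Little of these cardiac sums was Myl7 or Tnnt2, which had 3 and 2 counts over all sham below libraries. Sham above 22, 24 and 28, among the 14 with few, held 777 to 1955 CPM. Without the 5 neuron-rich libraries, sham below 28 and coarct below 23, 25, 29 and 30, 0 genes were called. The 14 with few held 1 sham below library, whose spread came from the other groups, so that the 13 calls there are no test between replicated groups. Pln differed by 2.86 (edgeR adjusted p = 0.986) within the 17 and by 4.46 within the 14.

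The interaction asked whether the difference between sites depended on coarctation, and no gene passed. Lgi4, a protein that Schwann cells secrete, measured 7.20 ± 0.963 CPM (SD, n = 6) and 14.7 ± 7.22 CPM (n = 6) in coarct above and below, and 11.3 ± 4.65 CPM (n = 5) and 7.37 ± 3.59 CPM (n = 5) in sham (edgeR adjusted p = 1.0). Lep gave an interaction of -0.02 on the log2 scale (SE 0.475), and Ucp1 one of 0.17 (SE 0.31). The lowest p belonged to Echs1, an enzyme of fatty acid oxidation, and Hsp90aa1, a heat shock protein (edgeR adjusted p = 1.0 for each), and Hsp90aa1 also lay apart between the sides of the mitochondrial rRNA split, by 2.58 on the log2 scale (limma adjusted p = 0.000632).

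Schwann cell genes had a more negative site difference in coarcted rats in 15 of 16 cases, by a median of -1.23, and erythroid genes in 11 of 11, by -1.44, with adjusted p = 0.196 for both with an estimated correlation. Macrophage genes did so in 18 of 19 cases, by -0.29, and nuclear respiratory chain genes were more positive in 35 of 36, by 0.19, with adjusted p = 0.481 and 0.442 with an estimated correlation. Neuron genes were more negative in 17 of 18 cases (median -1.73, adjusted p = 0.442 with an estimated correlation) and moved with the neuron sums of the 5 libraries below the ligature named above. The Schwann cell sum was also higher in the neuron-rich coarct below 23, 25, 29 and 30, at 478 to 734 CPM, than in 19 and 27, at 373 and 408 CPM. Sham above 22 had a Schwann cell sum of 710 CPM, against a median of 410 CPM in the other sham above libraries. EdgeR called 0 of 14556 genes, with 352 at an unadjusted p under 0.05 where 728 would arise by chance, and DESeq2, limma and the fits within each side of the rRNA split called 0, with 1 sham below library among the 14 with few such reads. Without the 5 neuron-rich libraries 1 gene was called, an uncharacterised locus chosen after its values were seen. That fit left only replicates 19 and 27 in coarct below.

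BAT of coarcted and sham rats was compared as fat away from the aorta, and no gene passed. Cox4i1, a subunit of cytochrome oxidase, measured 1476 ± 200 CPM (SD, n = 5) in coarct BAT and 1023 ± 108 CPM (n = 4) in sham BAT, a log2 difference of 0.71 (SE 0.241, edgeR adjusted p = 0.652), higher in 5 of 5 libraries. Postn, the matrix protein periostin, measured 377 ± 43.1 CPM against 604 ± 72.8 CPM, lower in 5 of 5 libraries (log2 difference -0.53, edgeR adjusted p = 0.652). Myoc, a secreted glycoprotein, had the lowest p, at 2.47 ± 0.631 CPM against 7.62 ± 4.76 CPM (edgeR adjusted p = 0.652). Lep, at 0.37, and Ucp1, at 0.10 on the log2 scale, differed by less than the spread between libraries.

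Nuclear respiratory chain genes lay higher in coarct BAT in 35 of 36 cases, by a median of 0.52, with adjusted p = 2.22e-08, or adjusted p = 0.864 with an estimated correlation. Coarct BAT replicate 29, which stood apart on the first principal component, had the highest sum of these genes, at 34320 CPM against 20150 to 28360 CPM in the other 4 and 19230 to 23330 CPM in sham BAT. It also had the lowest gene length slope, -0.41, and over the 9 libraries the sum moved with that slope (Spearman rho -0.833). Lymphatic endothelial genes lay lower in all 6 cases, by a median of -1.11, and 4 of them were lower adjusted over the list alone (adjusted p = 0.864 with an estimated correlation). Mmrn1, a matrix protein of lymphatic endothelium, measured 1.62 ± 0.993 CPM against 6.80 ± 5.77 CPM. Sham BAT replicate 22 held the highest summed lymphatic level, at 132 CPM against a median of 43.5 CPM in the others, and the highest Schwann cell sum, at 1376 CPM. The other sham BAT libraries had lymphatic sums of 34.5 to 45.0 CPM. Coarct BAT 19, 23, 27 and 29 had 21.0 to 25.8 CPM and coarct BAT 30 had 49.4 CPM (exact permutation p = 0.0635, adjusted p = 0.479). Macrophage genes lay lower in 17 of 18 cases, by -0.24, and Schwann cell genes in 11 of 15, by -0.58, both at adjusted p = 0.864 with an estimated correlation. Sham BAT 22 held 992 CPM of macrophage transcripts, whereas the other 3 of sham BAT, at 359 to 464 CPM, overlapped with coarct BAT, at 263 to 458 CPM. EdgeR called 0 of 13644 genes, with 928 at an unadjusted p under 0.05 against 682 by chance, and DESeq2, limma and the fits within each side of the rRNA split called 0. Without sham BAT replicate 22 the count was 1, Tma7, chosen after its values were seen. Cox4i1 differed by 0.47 and 0.90 within the 17 and the 14 libraries.

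PVAT above the ligature and BAT of sham rats were compared to set the fat of the aorta against classical brown fat. Mesothelial genes were far higher in PVAT: Msln, mesothelin (ENSRNOG00000019445, chromosome 10, start 15119663), measured 32.3 ± 9.40 CPM (SD, n = 5) against 0.0660 ± 0.132 CPM (n = 4), a rise of 8.43 on the log2 scale (SE 0.719, edgeR adjusted p = 8.83e-05). Lrrn4 and Upk3b, surface proteins of mesothelium, rose by 6.57 and 6.82. Cardiac genes rose as well, with Myl7 up by 10.36 (edgeR adjusted p = 0.000138) and 6214 counts of Tnni3 against 1, a ratio of 5370 with a 95% counting interval of 964 to 212000. Genes that fell included Postn, by 1.35 on the log2 scale (edgeR adjusted p = 0.000375), Hoxd8, a homeobox gene of body position, by 1.82, and Acer2, a ceramidase, by 1.26. Each of these was higher, or lower, than the BAT median in 5 of 5 libraries.

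Of 12 measured mesothelial genes, 6 rose over all genes and 12 adjusted over the list alone, and the list held at adjusted p = 0.00142 with an estimated correlation. Of 14 cardiac genes, 8 rose, with the list at adjusted p = 0.00562 with an estimated correlation, beside cardiac sums of 938 CPM above the ligature and 12.1 CPM in BAT. The white adipocyte list fell (adjusted p = 0.0215 with an estimated correlation), with 15 of 19 genes lower by a median of -0.24 and none past the test alone, among them Lep at 132 ± 52.0 CPM against 242 ± 45.9 CPM (edgeR adjusted p = 0.329). Skeletal muscle genes lay lower, by a median of -5.87, with 2 of 15, Actn3 and Pvalb, falling, 1, Mb, rising and 11 lower adjusted over the list alone, and adjusted p = 0.531 with an estimated correlation. Sham BAT 20, 22 and 24 held 799 to 1621 CPM of these transcripts, whereas sham BAT 26 held 228 CPM, less than sham above, at 265 to 429 CPM. Actn3, an actinin of fast muscle fibres, measured 0.876 ± 0.273 CPM against 54.5 ± 40.8 CPM, and its call was lost without any of 8 libraries (adjusted p 0.076 to 0.141), which were sham above 20, 22, 24, 26 and 28 and sham BAT 20, 22 and 24. The call of Pvalb was lost without any of the same 8 (adjusted p 0.0883 to 0.165). Ctgf, a matrix protein induced by stretch, rose by 1.76 (edgeR adjusted p = 0.0301), and the call was lost without any of sham BAT 20, 24 and 26 and sham above 26 and 28 (adjusted p 0.0581 to 0.107). The Hox and positional list had 2 of 26 genes that fell, Hoxd8 and Tbx15, a median of -0.14, a mean of 0.01 and adjusted p = 0.042, or 0.644 with an estimated correlation. Mb, the oxygen store of muscle, and Tbx15, a T-box factor, were chosen after their values were seen. Erythroid genes lay higher in 10 of 11 cases, by 1.36, with 6 higher adjusted over the list alone and adjusted p = 0.217 with an estimated correlation.

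EdgeR called 92 of 14190 genes, 64 higher and 28 lower, against 242 by DESeq2, 71 by limma and 59 without sham BAT replicate 20. Within the 17 libraries with mitochondrial rRNA reads the count was 1 and within the 14 with few 48, where Msln rose by 7.71 (edgeR adjusted p = 0.00848); within the 17 no fold is given for it, as both BAT libraries had 0 counts. Postn differed by -1.26 and -1.37 within the sides of the split, past the test in neither.

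PVAT below the ligature was set against BAT of sham rats in the same way. Msln measured 29.3 ± 15.0 CPM (SD, n = 5) against 0.0660 ± 0.132 CPM (n = 4), a rise of 8.37 on the log2 scale (SE 0.719, edgeR adjusted p = 9.71e-05). Foxp2, a forkhead transcription factor, rose by 3.26 (SE 0.348, edgeR adjusted p = 0.000323), and Abcc8, the sulfonylurea receptor of potassium channels, by 3.11 (edgeR adjusted p = 0.00242). Postn fell by 1.30 on the log2 scale (edgeR adjusted p = 0.00088), Cd14, a macrophage receptor for endotoxin, by 1.31 (edgeR adjusted p = 0.00563), and Cxcl13, a chemokine for B cells, by 2.03 (edgeR adjusted p = 0.0062). Ptges, a synthase of prostaglandin E, fell to 1.01 ± 0.510 CPM from 4.74 ± 1.77 CPM (edgeR adjusted p = 0.0119). All of these held in 5 of 5 libraries against the BAT median.

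Of 35 matrix structure genes, 5 fell over all genes (Postn, Col5a2, Col1a1, Col3a1 and, chosen after its values were seen, Col5a3), and 17 fell and 1 rose adjusted over the list alone, with adjusted p = 1.89e-10, or adjusted p = 0.406 with an estimated correlation. Sham BAT 22 and 24 held 26760 and 18150 CPM of these transcripts, against 8682 and 8215 CPM in the other 2 and 4745 to 8457 CPM below the ligature. Col1a1 fell by 2.45 (SE 0.494, edgeR adjusted p = 0.0327), at 487 ± 201 CPM against 2792 ± 2527 CPM, and the call was lost without any of sham below 20, 22 and 28 and sham BAT 22 and 24 (adjusted p 0.0631 to 0.105). Col3a1, a fibrillar collagen chain of soft tissue, fell by 1.59 (edgeR adjusted p = 0.0358), a call lost without any of sham below 20, 22, 26 and 28 and sham BAT 22 and 24 (adjusted p 0.0565 to 0.111). Col5a2, another fibrillar collagen chain, fell by 1.22 (edgeR adjusted p = 0.0159; 0.0575 without sham BAT 22). Of 12 mesothelial genes, 6 rose over all genes and 12 adjusted over the list alone, with adjusted p = 0.00412 with an estimated correlation. Macrophage genes lay lower in 18 of 19 cases, by a median of -0.59, with Cd14 the member that fell and adjusted p = 0.494 with an estimated correlation. Sham BAT replicate 22 held 992 CPM of macrophage transcripts, and the other 3 BAT libraries, at 359 to 464 CPM, overlapped with sham below, at 199 to 477 CPM. Nuclear respiratory chain genes lay higher in 33 of 36 cases, by 0.19, and hypoxia and glycolysis genes in 17 of 23, by 0.33, with adjusted p = 0.537 and 0.406 with an estimated correlation. The respiratory chain sum moved with the gene length slope over the 9 libraries (Spearman rho -0.867). Cardiac genes had a median of 0.72 and adjusted p = 0.341, with none past the test.

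EdgeR called 115 of 14190 genes, 54 higher and 61 lower, against 327 by DESeq2, 34 by limma, 66 with the spread of both groups alone and 0 within the 17 libraries with mitochondrial rRNA reads. The 14 with few held 1 sham below library, whose spread came from the other groups, so that the 8 calls there are no test between replicated groups. With the title number as a block, Col1a1 and Col3a1 were no longer called (edgeR adjusted p = 0.093 and 0.0866), and Lep differed by -1.42 (edgeR adjusted p = 0.0107). The skeletal muscle and immediate early lists were then called (camera adjusted p = 0.0101 and 0.0153, from 0.104 and 0.441) and the interferon list was not (0.253, from 0.0442). Without the block, an estimated correlation left 1 list called in this comparison, the mesothelial one. The count without sham below replicate 20 was 47 and without 22 it was 54, and without sham BAT replicates 20, 22, 24 or 26 it was 53, 65, 64 or 58. Foxp2 differed by 3.66 and 3.04 and Col1a1 by -2.14 and -3.41 within the 17 and the 14, past the test in the 17 for neither.

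**Figure D3:**
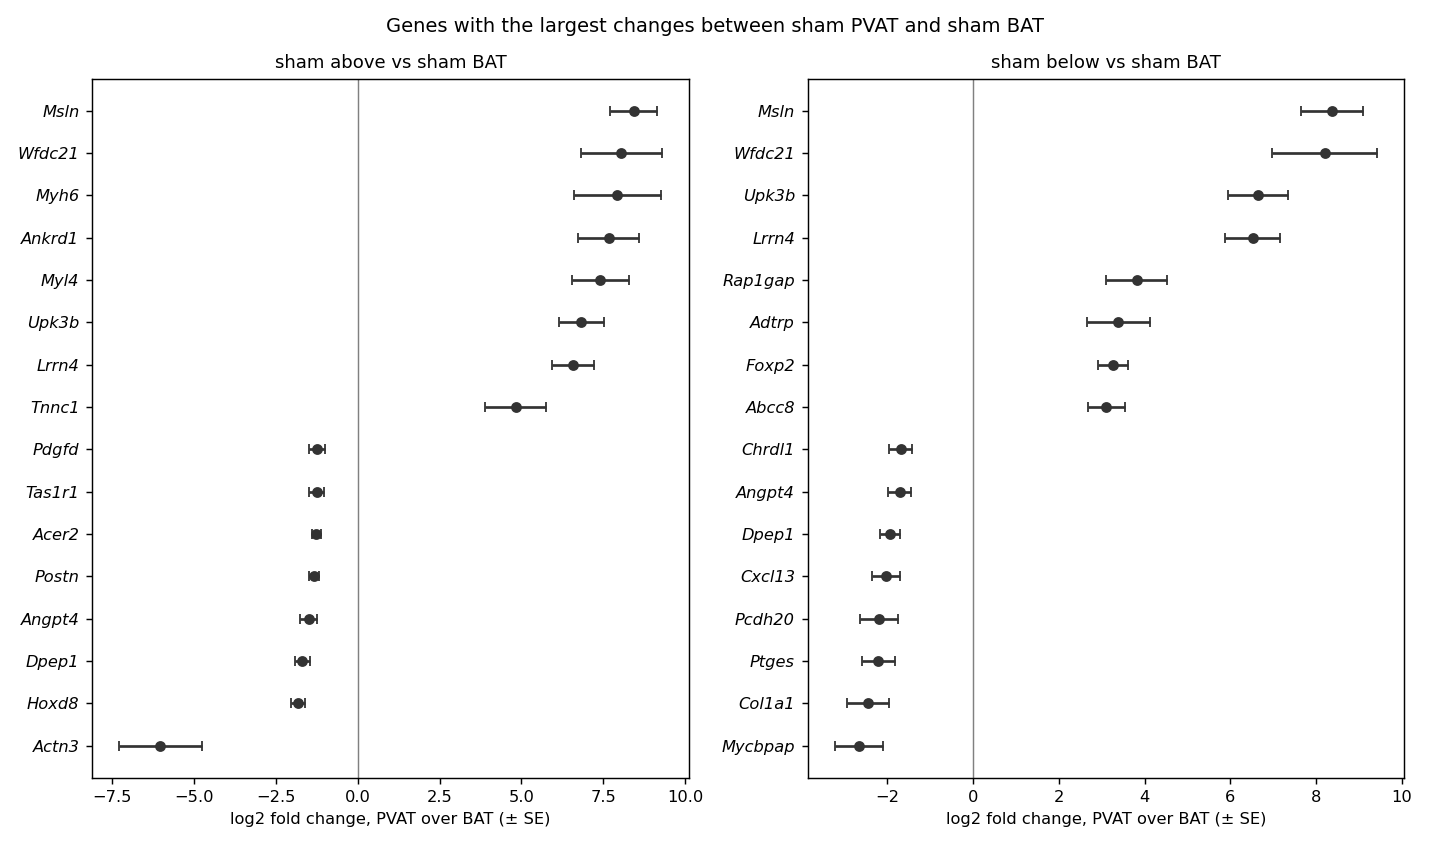
Largest log2 fold changes ± SE of sham PVAT against sham BAT among called genes, above the ligature and below it, in panels with different horizontal ranges. The SE was derived from the F statistic of each gene's test. Msln rose by 8.43 above and 8.37 below, and the bar of Wfdc21 rests on 3 counts in BAT.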

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

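The tests of cardiac and neuron transcripts, of coarctation as their source, of the rRNA split and of gene length, and the splits that part every pair, were chosen only after the result was seen, and the list of nucleolar genes was written after the genes of that split were known. The counts of the 100 splits of the libraries and the test of swapped numbers were chosen before, the latter after correlations over all genes had been seen.

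Single libraries stood apart from the rest of their group in 38 of 257 groups tested by the gap between the extreme library and its nearest neighbour as a share of the group's range. Normally distributed values would give about 1 in 20, or 12.9 groups. CPM values need not be normal, all flags were at the high end, and several flags came from the same library. The 38 are therefore no measure of an excess over chance. In coarct above, replicate 19 was highest for summed cardiac transcripts (gap 0.738, 3072 CPM against a median of 598 CPM in the others), Tnnt2 (0.714), Ankrd1 (0.658), Actc1 (0.763), Myl4 (0.762) and Myh6 (0.739), and replicate 29 for skeletal muscle (0.919, 2431 against 309 CPM). In coarct below, replicate 25 was highest for cardiac (0.988, 675 against 9.89 CPM), skeletal muscle (0.937, 3834 against 271 CPM) and thymus transcripts (0.631), Tnnt2 (0.765), Actc1 (1, with 0.884 CPM against 0) and Myh6 (0.775). Also in coarct below, replicate 19 had the highest share of mitochondrial counts (0.658, 45.45 against 37.25 percent) and replicate 30 the highest Myh11 (0.644). In coarct BAT, replicate 19 was highest for skeletal muscle (0.9, 7088 against 281 CPM), replicate 27 for squamous epithelium (0.719, 0.493 against 0.0488 CPM) and replicate 30 for lymphatic transcripts (0.831, 49.4 against 23.6 CPM). In sham above, replicate 22 was highest for Schwann cell transcripts (0.793, 710 against 410 CPM) and Actn3 (0.759), replicate 26 for lymphatic transcripts (0.827, 180 against 63.7 CPM), Ctgf (0.734) and Pdgfra (0.739), and replicate 20 for Pvalb (1, with 0.310 CPM against 0). In sham below, replicate 28 was highest for neuron transcripts (0.991, 667 against 15.5 CPM) and Mycbpap (0.788), replicate 22 for Tnni3 (0.794) and replicate 26 for Pln (0.81). In sham BAT, replicate 22 was highest for Schwann cell (0.932, 1376 against 444 CPM) and lymphatic transcripts (0.893, 132 against 43.5 CPM), Pdgfra (0.898), Msln (1, with 0.264 CPM against 0), Lrrn4 (0.931), Tnni3 (1, with 0.0377 CPM against 0), Wfdc21 (1, with 0.113 CPM against 0), Angpt4 (0.945) and Chrdl1 (0.941), and replicate 20 for Myl4 (0.897).

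Cardiac transcripts marked PVAT above the ligature and neuron transcripts 5 libraries below it. Coarctation as the whole source of the cardiac transcripts is argued against by the sham libraries, where 6 of 13 list members were called between the sites. Cardiac muscle cells in the above samples remain a candidate source, since 15 genes of the list rose and fell together over the above libraries with a median pairwise Spearman rho of 0.713 across libraries, and sympathetic ganglion cells in the below samples likewise, with 0.809 over 20 genes. Whether coarctation raised the neuron transcripts cannot be told apart from uneven dissection, since 2 coarct below libraries exceeded the highest sham below library and the exact permutation p was 0.13. Regional differences of the fat itself stay open and were not tested.

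All 31 libraries split by mitochondrial rRNA, with 12S at 42.05 to 79.01 CPM in 14 and 2572 to 7253 CPM in 17, and 77 of 15018 genes lay apart between the sides, among them 8 of 8 Rrp genes of rRNA processing by a median log2 difference of 2.68. Surgery or site as the cause is argued against by 6 of 6 groups with libraries on both sides (Fisher's exact p = 0.907), while ribosome biogenesis cannot be told apart from other causes: the list of 26 other nucleolar genes, with a median of 0.0948, left out Nop2, Emg1, Exosc5 and Dis3, rRNA processing genes that lay apart by 2.44, 1.07, 1.32 and 0.85. Removal of rRNA reads that differed between libraries may be the cause, since 16S lay higher by 2.35 and a 5.8S gene by 2.63 in the 17 libraries. This cannot be told apart from other causes either, since the 2 genes of 5S rRNA differed by -0.345 and -0.364, and how the Rrp genes would follow was not tested. No biological cause beyond surgery, site and ribosome biogenesis was tested.

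Sham above replicate 20 and sham below replicate 24 deviated alike from their groups, with a correlation of 0.749 over 11276 genes. Swapped numbers of sham above 20 and 24 are argued against on the 200 genes that varied most between the other numbers, where crossed pairs had a lower mean correlation than own pairs by a difference of -0.493 (0.0549 against 0.548), whereas over all genes the crossed pairs had the higher mean, 0.446 against -0.142. A trend on gene length as the whole cause is argued against, as the correlation was 0.718 once that trend was removed. The sources of this deviation stay open, and no biological explanation was tested.

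Each comparison was also run on 100 splits of its libraries into groups of the same sizes, the real one included. Fewer splits than a share of 0.05 reached the real count for PVAT above against BAT in shams (92 genes, 1 split, highest other 42). The same held for PVAT below against BAT (115 genes, 1 split, highest other 101). It also held for the sites in coarcted rats (15 genes, 2 splits, highest other 18). For the sites in shams it held narrowly (10 genes, 4 splits, highest other 104), and chance is not excluded there. All these splits ignored the title numbers. The split with 18 genes set coarct above replicate 30, which lacks cardiac transcripts, with the libraries below. Of the 32 splits that part all 6 pairs of coarct above and below, only the real one called as many (highest other 14), also with the title number as a block (42 genes, highest other 37). The split with 37 genes exchanged the sites of replicates 19 and 27, which lack neuron transcripts below, and the remaining splits of the 100 kept both libraries of some pairs on 1 side. For sham below and BAT 16 splits part all 4 pairs, too few for a share under 0.05 (115 genes, highest other 9, and 154 and 9 with the block). For the comparisons with 0 genes every split gives at least as many, so that 100 of 100 says nothing on chance; the highest others were 1 for coarct above against sham above, 1 for coarct below against sham below, 1 for the interaction and 263 for BAT. Of the sites in shams, 3 splits with 43, 85 and 104 genes called several times the real 10, each with sham above 20 and sham below 24, which deviated alike, on 1 side. For BAT, where the real split called 0, other splits called 263, 182 and 22. Both point to a structure among the samples.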

How the results depend on the processing

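The fits within the sides of the rRNA split, with the muscle and neuron sums as covariates, without 3 libraries apart on the first principal component and without 5 neuron-rich libraries were chosen only after the data were seen. Counts are given in the order coarct above with sham above, coarct below with sham below, the sites in coarcted rats, the sites in shams, the interaction, BAT, and PVAT above and below with BAT in shams, where edgeR called 0, 0, 15, 10, 0, 0, 92 and 115 genes and 12, 12, 14, 24, 17, 5, 16 and 14 lists. DESeq2 size factors, and a minimum log2 change of 1, kept every gene count within 1.5 times. The DESeq2 Wald test gave 6, 1, 235, 44, 242 and 327 genes for the comparisons other than the interaction and BAT. limma on log2(FPKM + 1) gave 4 for the sites in coarcted rats and 34 for PVAT below with BAT; the spread of the compared groups alone gave 5 and 66. Within the 17 libraries with mitochondrial rRNA reads, 24 and 6 lists were called for the surgery comparisons above and below, and 0 and 0 genes for the sites in coarcted rats and shams, and 1 and 0 for PVAT above and below with BAT. Within the 14 with few, the values were 6 lists for surgery above, 9 genes for the sites in coarcted rats, 15 lists for the sites in shams, 8 lists for BAT, and 48 and 8 genes for PVAT above and below with BAT; sham below then had 1 library, assumed to vary like the other groups. An estimated correlation left 0, 0, 4, 1, 0, 0, 3 and 1 lists. The covariates gave 1 gene and 6 lists for surgery below, 1 gene for the sites in coarcted rats, and 5 genes and 7 lists for the sites in shams. These covariates contain muscle and neuron genes under test, so that a loss of calls of such genes is largely built in. Without the neuron-rich libraries, surgery below had 1 gene and 6 lists, and the sites in coarcted rats 1, in shams 0 and the interaction 1 gene. These fits left only replicates 19 and 27 in coarct below. For BAT, lists numbered 12 without a filter, 3 with the spread of all libraries and 12 without the libraries apart on the first component. Outside the settings whose fewer samples or calls are by construction, the cause was not tested.

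Leaving out each library in turn gave 0 to 0, 0 to 169, 12 to 185, 8 to 23, 0 to 0, 0 to 1, 59 to 100 and 47 to 157 genes, and 8 to 19, 8 to 14, 9 to 18, 18 to 24, 11 to 22, 2 to 12, 12 to 15 and 11 to 15 lists. The 169 genes came without sham below 28, the 185 without coarct below 19, the 23 without sham above 20, the 59 without sham BAT 20 and the 47 without sham below 20. Titles give libraries of several sites one number but no source states that these share a rat: 21 of 29 same-number pairs correlated above 0.1 (median 0.294, against -0.061 over 132 pairs of other numbers). In shams 3 of 5 such pairs of the sites and 1 of 4 of PVAT above with BAT did so, and 20 of 31 libraries correlated best with their own number. A block for that number gave 42 genes for the sites in coarcted rats, 56 in shams, and 110 and 154 for PVAT above and below with BAT. In the 2 comparisons where every same-number pair correlated above 0.1, it changed Myh6 (edgeR adjusted p = 0.128) and the calls given in the report. No other call of a gene named by the rule or of a list changed there. Changes of calls in the other comparisons are not given. No named gene that was called in the main fit or in an alternative changed direction between them. Changes of direction of genes called in neither were not counted. In all, 53, 18, 76 and 99 values were no longer past the threshold for the sites in coarcted rats, the sites in shams and PVAT above and below with BAT. In simulated data, changes of 1.5-fold were found for 11 of 49 genes for surgery above and 0 of 49 in BAT, and of 4-fold for 41 of 50 and 44 of 50, so that changes of 1.5-fold were mostly missed.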

Other observations

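The tests here are list tests fixed in advance, apart from that of the gene Car3; which lists to describe, and Car3, were chosen only after the results were seen. In sham PVAT, skeletal muscle genes were lower above than below the ligature in 12 of 13 cases, by a median of -4.04, with adjusted p = 0.452 with an estimated correlation. Sham below replicates 22 and 28 held 1297 and 832 CPM of these transcripts, and the other 3 libraries below, at 273 to 408 CPM, lay within the range above, 265 to 429 CPM. Vascular smooth muscle genes lay higher above in 16 of 20 cases, by 0.26, and inflammatory cytokine and adhesion genes in 18 of 23, by 0.24, with adjusted p = 0.28 and 0.406 with an estimated correlation. Circadian clock genes lay lower above in 15 of 17 cases, by -0.13, and hypoxia and glycolysis genes in 18 of 24, with adjusted p = 0.28 for both with an estimated correlation. Heat shock, glucocorticoid-responsive and lymph node stroma genes were called in no comparison, with lowest adjusted p of 0.282, 0.323 and 0.466.

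Against BAT, sham PVAT below the ligature had higher fatty acid and triglyceride synthesis genes in 14 of 20 cases, by a median of 0.39, with adjusted p = 0.517 with an estimated correlation. Antigen presentation genes lay lower in 16 of 17 cases, by -0.39, and interferon response genes in 23 of 29, with adjusted p = 0.456 and 0.665 with an estimated correlation. Sham BAT 22 had the highest antigen presentation sum, 2294 CPM, and the other 3, at 1213 to 1531 CPM, overlapped with sham below, at 878 to 1589 CPM. Of the white adipocyte list 1 gene fell, Car3, a carbonic anhydrase of fat chosen after its values were seen (edgeR adjusted p = 0.0356). In coarct BAT, matrix structure genes lay lower in 23 of 35 cases, by a median of -0.24, with adjusted p = 0.864 with an estimated correlation. Sham BAT 22 and 24 held the highest sums of that list, 26760 and 18150 CPM, and the other 2, with 8682 and 8215 CPM, lay below 4 of the 5 coarct BAT libraries, at 10170 to 15000 CPM.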
